A study of Caenorhabditis elegans with 2 samples.

How the data were processed

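AMA-1 chromatin immunoprecipitation followed by sequencing was analysed in 2 biological replicates of whole L1 larvae of strain N2, which per the labels were pooled male and female animals of unknown age, with a size range of 150 to 350 whose unit is not given in the sources used here. Both replicates formed 1 group. Lists of regions on builds ce10 and ce11 were used, and alignments, reads and coverage tracks were not analysed here. Per the submitters' processing notes, each replicate's list of 30000 regions was derived from its alignments and a control, a further list from the pooled alignments of both replicates, and a thresholded list from an irreproducible discovery rate (IDR) analysis of them. The peak caller, its version, the IDR threshold, the antibody's source, the control's preparation and the sequencing depth are not given in the sources used here. The deposited signal value of each region, from the authors' peak caller, was used without rescaling, and signals of separate libraries were compared by rank, by presence, side by side and, at consensus peaks, by a correlation of log2 signal. The deposited −log10 q-value of each region was used only for alternatives, because it had an upper limit shared by 5066 regions of replicate 1, 2136 of replicate 2 and all consensus peaks. Summits were taken from the offset in each list. All 1328 consensus regions on ce11, and all 1380 on ce10, were also the highest-signal regions of the pooled list, so pooled signal alone sets which regions the consensus holds.

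Genes and transcripts came from Ensembl release 115 on WBcel235, the assembly also called ce11, with 19973 protein-coding genes. The unique share was the percent of 31-base words found once in the genome, over a gene and its 500 bp upstream for gene lists and classes and for the limit of 90%, over the listed region for a peak, and inside the gene alone for SL2 genes and, in the closing comparison of tRNA and snRNA genes, for those. A gene carried a peak where a summit lay between 500 bp upstream of its 5' end and its 3' end, and a summit could serve several genes. Summits were placed, in this order, into 5' ends (within 500 bp), 3' ends, gene bodies, non-coding RNA genes and intergenic sequence. These shares and those of the 9 gene classes were compared with 1000 random placements on the same chromosome by two-sided permutation tests, with Benjamini-Hochberg adjustment over the classes. The fixed design did not name piRNA genes, which were set apart from the other non-coding genes once the annotation was read. The overlap of the replicates used as many highest-signal regions as the consensus holds and 1000 circular shifts. X-linked and autosomal genes, and each of 26 lists of protein-coding genes against all others, were compared by two-sided Fisher's exact tests, the lists with Benjamini-Hochberg adjustment and a threshold of 0.05. Signal of X-linked and autosomal peaks was compared by 100000 permutations. Bootstrap intervals used 1000 samples, and all random seeds were fixed. A count of 0 was given the limit of 3 counts of the total. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

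The design, the gene lists, the tests and most alternatives were fixed before the data were examined. The text names the 20 protein-coding genes of highest signal among consensus peaks that met a region above the median signal of both replicate lists. It also names the 3 highest of each list and of each non-coding class. Named too are the 5 highest genes on X of any class, the 5 highest protein-coding ones and ama-1. The last set is the 5 peaks that differed most in rank between replicates, among those found in both lists, and examples come from each set. Genes named outside that rule, other than those that share a peak with a named gene, are said to be so. The lists were regular expressions on gene symbols, and microRNA symbols were matched without their species prefix. Chosen after the data were seen were the exact sign tests of lists between replicates, Fisher's exact tests of the same splits against those of other protein-coding genes, the SL2 and SL1 counts, the test of upstream positions, the restriction to peaks strong in both replicates and the restriction to genes with at least 90% unique sequence. A further 4 lists of moult-linked families were written after the difference between replicates was seen and before their own values were.

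Alternatives were the consensus peaks above their median signal, each replicate's own highest-signal regions, windows of 250 and 1000 bp, placement over all chromosomes, other rules for overlap, for assigning peaks to genes and for ranking, 10000 random lists matched on gene length, list mean ranks over the full lists, and build ce10. The highest-signal regions of the pooled list were the consensus itself, so that alternative changed nothing by construction.

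The computations were tested on simulated data. With 12 of 82 genes of a list given a peak, the list was called in 100% of sets, and with 300 of 1328 peaks moved to 5' ends, 37.3% were found there where 37.3% were due. A planted overlap of 50% was recovered as 50.4%. With peaks planted at 12 snRNA genes, 17 of 129 carried a peak, and the permutation test gave an adjusted p of 0.0180. On 200 sets of random peaks the 5' end test fell under the threshold in 10. Fisher's exact test of the lists made 49 calls above and 107 below over 200 sets of random peaks. Of these, 32 were pan-neuronal and synaptic genes above and 89 chemoreceptors below, because long and short genes meet random summits at different rates. Among the 7 lists called above in the consensus, only heat shock and chaperones was called above on random peaks, in 1 set. The length-matched test made 2 calls in all, and its values are therefore given beside those of Fisher's exact test.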

Results

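AMA-1, the large subunit of RNA polymerase II, was immunoprecipitated from whole L1 larvae of N2, the wild-type strain of Caenorhabditis elegans, and the recovered DNA was sequenced. The 2 biological replicates were mixed-sex populations of unknown age and formed 1 group, so the comparisons are between places in the genome, between sets of genes and between the replicates. Each replicate, and the pool of both, had a list of 30000 regions, and a thresholded consensus list held 1328 regions on build ce11. The peak caller's signal ran from 34.3 to 803 in the consensus list, with a median of 47. Median signal over the full lists was 6.42 in replicate 1 and 4.53 in replicate 2. The number of reads behind each list is not given in the sources used here, so the sequencing depth is unknown, and the intervals given with shares are exact 95% binomial intervals that cover only the counting of genes or peaks. Genes and peaks are not independent replicates, so each p-value describes these 2 libraries.

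The 3 highest AMA-1 signals in the genome lay on genes for SL2, the spliced leader RNA that is joined to downstream transcripts of operons. They were sls-2.4 (chromosome I, peak 4172047 to 4172543), with a signal of 803, sls-2.2 (chromosome II, peak 5543434 to 5543928), with 793, and sls-2.1 (chromosome II, peak 5844715 to 5845214), with 694. The replicates gave 465 and 333 at sls-2.4, 495 and 307 at sls-2.2, and 404 and 297 at sls-2.1, for replicates 1 and 2. Of the 18 annotated SL2 genes, 9 carried a consensus peak by the window rule. Consensus summits also lay just past the 3' ends of sls-2.7, sls-2.14, sls-2.16 and sls-2.17. The rule counts these genes as without a peak, although their peaks are among the red points of the figure where both replicates had a region. The SL2 genes share sequence to different degrees. Of the 31-base words inside the gene 73.8% were unique in the genome at sls-2.4, 50% at sls-2.2 and 38.8% at sls-2.1. This share ran from 21.25% at sls-2.12 to 100% at sls-2.8, sls-2.9, sls-2.16 and sls-2.18. Over the whole listed region of the peak it was 95.1% at sls-2.4, 87.7% at sls-2.2 and 85.7% at sls-2.1. None of the 12 SL1 genes carried a peak, but the median unique share of their windows was 3.01%, so a signal there was hardly detectable. The SL2 and SL1 genes were singled out after their values were seen.

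**Figure D1:**
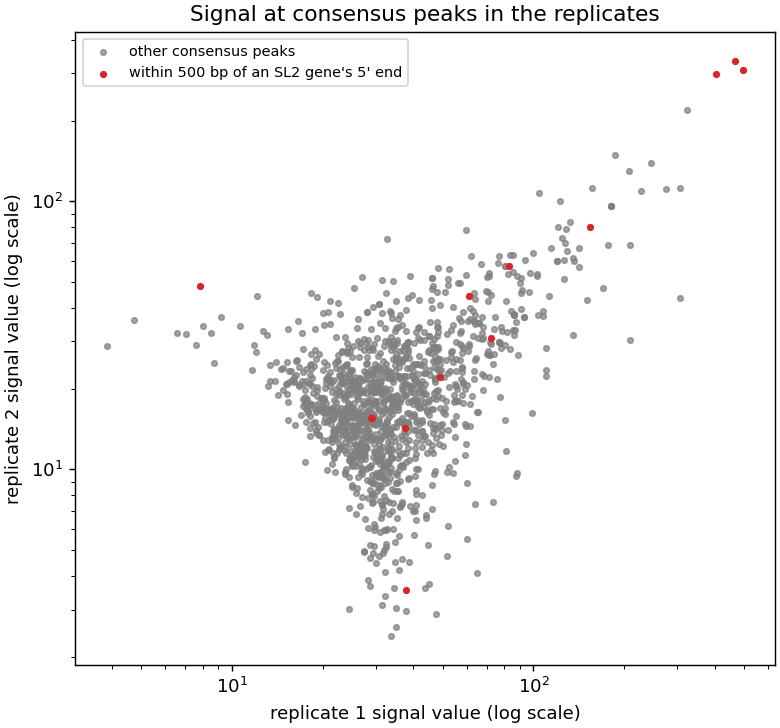
Signal of replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), in the peak caller's units, at consensus peaks found in both replicate lists, 1 point per peak. Red points lie within 500 bp of the 5' end of an SL2 gene, and the 3 highest of them had 404, 465 and 495 in replicate 1.

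Consensus peaks gathered at the 5' ends of protein-coding genes. Of the 1328 summits, 581 (43.8%, interval 41.1 to 46.5) lay within 500 bp of a 5' end, 2.29 times the 19.1% of random placements. The 3' ends of genes also held more summits than random placement, 276 (20.8%) against 12.3%. Fewer lay inside gene bodies, 270 (20.3%) against 44.2%, and outside annotated genes, 153 (11.5%) against 22.4%. Non-coding RNA genes away from protein-coding ones held 48 (3.61%) against 2.06%. Each of these 5 shares differed from 1000 random placements on the same chromosome with a two-sided permutation p of 0.002, the smallest they can give. With a window of 1000 bp the share at 3' ends was 17.2% and no longer differed from random placement (permutation p = 0.146). Summits are placed at 5' ends first, and with that window 5' ends held 59.1% of them.

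**Figure D2:**
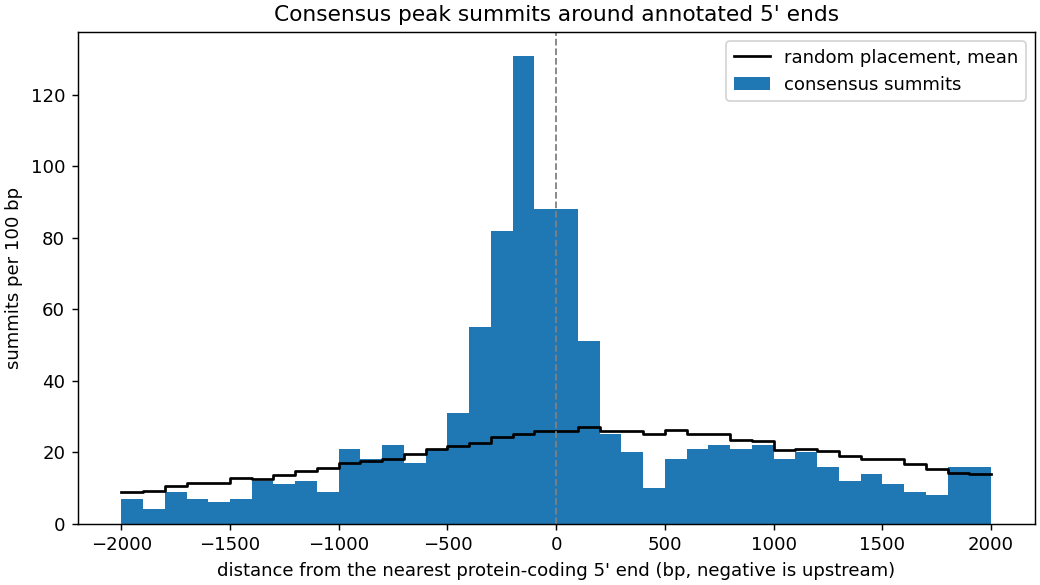
Number of consensus summits per 100 bp (y axis) by distance from the nearest protein-coding 5' end in bp (x axis, negative is upstream). Bars are the observed summits and the line is the mean of 50 random placements; among the 581 summits within 500 bp the median distance was -109 bp.

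Within the 581 peaks at 5' ends, 387 summits (66.6%, interval 62.6 to 70.4) lay upstream of the annotated end, with a median position of -109 bp and quartiles at -224 and 60 bp. A binomial test of upstream against downstream positions, chosen after the positions were seen, gave a two-sided p of 9.00e-16. Annotated 5' ends in this species often mark the trans-splice site, so these distances are from the annotation and not from the place where transcription starts. Of the consensus regions, 88.2% had the same width, and the median width was 340 bp. Coverage was not analysed, so these positions and the shares by place describe listed summits and not the spread of polymerase along genes.

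A consensus peak was carried by 934 of the 19973 protein-coding genes (4.68%, interval 4.39 to 4.98), where a gene's window ran from 500 bp upstream to its 3' end. The 20 genes with the highest signals ran from 157 to 417, and their peaks ranked among the first 47 regions of replicate 1 and the first 73 of replicate 2. They included drap-1 (388), which encodes a transcriptional corepressor subunit, mdt-26 (340), which encodes a subunit of the Mediator complex, tos-1 (333), and ufbp-1 (281). Lower in the same set were wwp-1 (207), which encodes a ubiquitin ligase, ego-1 (189), an RNA-dependent RNA polymerase gene, cdc-48.1 (188), which encodes an AAA ATPase, and mnk-1 (157), a kinase gene. F58G1.7 held the highest signal of the 20 (417) at a summit in an intron, in a peak that was 78.2% unique. Summits lay upstream of the gene in 9 of the 20, in an intron in 5, in a coding exon in 4 and in a 5' UTR in 2. Of the 20 peaks, 11 were also inside the window of another gene, in 5 cases a protein-coding one, so their assignment is uncertain. Among these were the peaks of F58G1.7, shared with F58G1.11, drap-1, shared with F40F9.15, mdt-26, shared with ift-43, and Y75B8A.23 (229), shared with sls-2.8 and tim-1. Of all consensus peaks, 822 fell in the window of 1 protein-coding gene, 146 in 2 or more and 360 in none. The polymerase subunit's own gene, ama-1, had no consensus peak, and the highest pooled signal in its window was 14.3 (8.51 in replicate 1 and 6.21 in replicate 2).

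Genes for short structured RNAs carried peaks far more often than random placement gave. An snRNA gene had a peak in 18 of 129 cases (14%, 16.5 times random placement), a snoRNA gene in 41 of 346 (11.8%, 13.4 times) and a microRNA gene in 24 of 261 (9.20%, 12.2 times). The microRNA gene mir-52 held the fourth highest signal of the consensus list (532; chromosome IV, peak 14033780 to 14034234), and mir-54, mir-55 and mir-56, the first named after its value was seen, shared 1 peak (147) inside F09A5.3. Of the 41 snoRNA genes with a peak, 21 lay inside a protein-coding gene, as did 216 of all 346. The tRNA genes, which RNA polymerase III transcribes, carried a peak in 18 of 612 cases (2.94%, 4.55 times random placement), with T03E6.t1 highest (82.9). Other non-coding genes did so in 189 of 8058 cases (2.35%, 2.75 times). Pseudogenes (8 of 2128, 0.144 times, highest F07H5.5 with 135) and piRNA genes (24 of 15363, 0.261 times, highest 21ur-14981 in the window of ego-1) lay below random placement. Each of these 7 classes had an adjusted permutation p of 0.00257, from an unadjusted p of 0.002, the smallest that 1000 placements can give. Protein-coding genes as a class were at 0.982 times random placement (adjusted permutation p = 0.369). The class was below random placement without replicate 1 (0.889 times, adjusted permutation p = 0.00257) and with a 250 bp window (0.857 times, 0.00225). It was above with interval overlap (1.08 times) and with only summits within 500 bp of a 5' end (2.57 times), with an adjusted permutation p of 0.00225 for each. No peak was found at the 20 rRNA genes, but 0 of 20 allows a share of up to 15%, and the median unique share of their windows was 2.34%. Without replicate 1, the tRNA class was at 1.95 times random placement and was no longer called (adjusted permutation p = 0.160), nor was it among peaks strong in both replicates (2.67 times, adjusted permutation p = 0.141).

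In the consensus list, 5 of the 26 lists carried peaks more often than other protein-coding genes by both Fisher's exact test and the length-matched test. Cytosolic ribosomal protein genes had 34 of 82 (41.5%, interval 30.7 to 52.9), against 4.52% of other protein-coding genes, with rpl-3 (139), rpl-20 (127) and rps-12 (102) highest. Heat shock and chaperone genes had 15 of 65 (23.1%), with cct-1 (91.8), a chaperonin subunit gene, and hsp-16.2 (88.4), whose peak, 87.5% unique, was also in the window of hsp-16.41. The peak of hsp-110 (92.5) was at its 3' end and also in the window of ufbp-1. Genes of the mitochondrial respiratory chain and ATP synthase had 14 of 71 (19.7%), led by cox-5A (144), a cytochrome oxidase subunit gene. Translation factor genes had 9 of 44 (20.5%), with iff-2 (96.1), eif-3.C (77.6) and eef-1A.1 (71). V-ATPase genes, for the proton pump of acidic organelles, had 7 of 21 (33.3%), with vha-1 (49), vha-12 (44.3) and vha-2 (40.9). Fisher's exact test against other protein-coding genes, Benjamini-Hochberg adjusted over 26 lists, gave adjusted p = 1.31e-22, 2.00e-06, 2.81e-05, 0.000618 and 0.000162 for these 5 lists in that order. Random lists of the same gene lengths gave adjusted permutation p = 0.00104 for the first 4 and 0.00173 for V-ATPase. In the highest-signal regions of the replicates, the counts were 27 and 22 for ribosomal proteins, 18 and 13 for chaperones, 13 and 10 for the respiratory chain and 9 and 6 for translation factors. V-ATPase had 4 in replicate 1, where it was not called (adjusted p = 0.0535, Fisher's exact test), and 6 in replicate 2. Its call also ended among consensus peaks above their median signal (adjusted p = 0.787) and among those strong in both replicates (adjusted p = 0.286), both smaller sets, by Fisher's exact test.

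Mitochondrial ribosomal protein genes (8 of 69, 11.6%, highest mrps-7 with 74.9) and proteasome genes also passed Fisher's exact test, with adjusted p = 0.0431 and 0.0460. The proteasome genes with a peak were 5 of 33 (15.2%), namely rpn-3 (63.3), rpt-2, rpn-6.1, pbs-3 and rpn-2, the last 2 named after their values were seen. Both calls ended against lists of the same gene lengths (adjusted permutation p = 0.0510 for each), in each replicate alone, with a 250 bp window, among consensus peaks above their median signal and among those strong in both replicates. The proteasome call also ended among genes with at least 90% unique sequence and with summits near 5' ends only, and that of mitochondrial ribosomal proteins with each summit given to the nearest 5' end. Splicing and mRNA export genes had 6 of 49 (12.2%, adjusted p = 0.0613, Fisher's exact test), led by prp-8 (47), and passed with a 1000 bp window (adjusted p = 0.0349), with summits near 5' ends only (0.0169), with interval overlap (0.00424) and by mean rank over the full lists.

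Chemoreceptor and F-box genes rarely carried a peak. Of 1312 chemoreceptor genes, which are expressed mostly in sensory neurons, 6 did (0.457%, interval 0.168 to 0.993), where lists of the same gene lengths held 50.1 on average. The peak nearest srh-2 (89.5) was also in the window of icl-1, and that of srh-269 (82.9) was also in the window of a tRNA gene. Of 322 F-box genes, fbxb-72 (92.3, in a peak 88.3% unique) and fbxb-85 (58.9) carried one, where 12.4 were found in lists of the same lengths. Adjusted p was 2.54e-19 and 0.000204 by Fisher's exact test, and 0.00104 and 0.00520 by the length-matched permutation test. The replicates gave 7 and 6 chemoreceptor genes and 2 and 2 F-box genes. The F-box call ended among consensus peaks above their median signal (adjusted p = 0.166, Fisher's exact test) and among those strong in both replicates (adjusted p = 0.227), both smaller sets. C-type lectin genes had 3 of 240, clec-264 (96.3), clec-1 (61.9) and clec-140 (48.4), with adjusted p = 0.0257 by Fisher's exact test, and the call ended against lists of the same lengths (adjusted permutation p = 0.0510), without replicate 2 (adjusted p = 0.139), in both of these smaller sets, with a 250 bp window and with each summit given to the nearest 5' end. Fisher's exact test alone is weak evidence for the chemoreceptors, since it also placed them below other genes in 89 of 200 sets of random peaks, but it did so for F-box genes in 4 sets and for C-type lectins in 1.

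**Figure D3:**
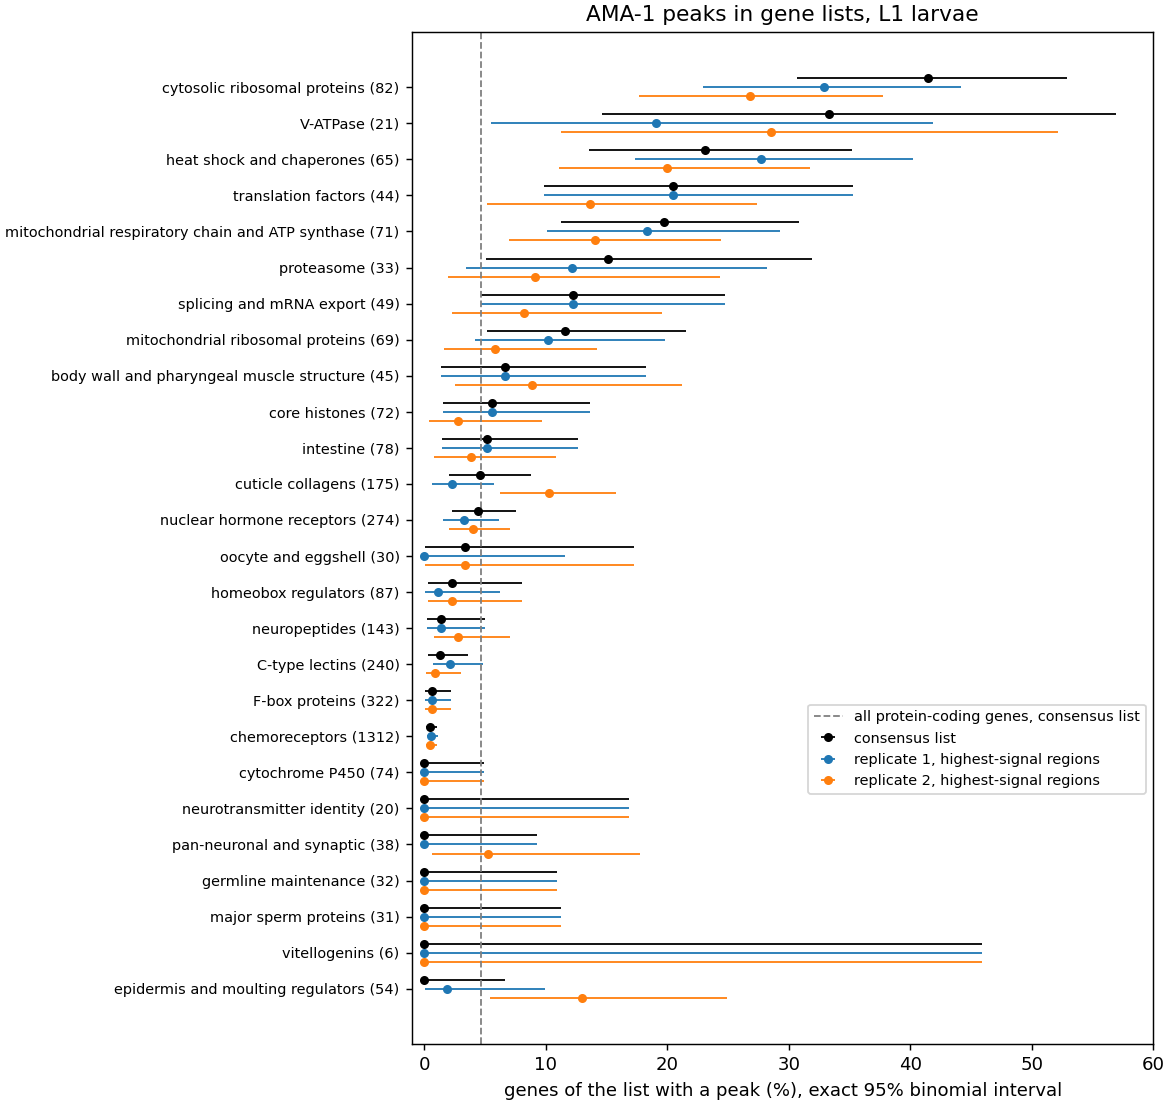
Percent of the genes of each list with a peak (x axis), with exact 95% binomial intervals, for the consensus list (black) and the highest-signal regions of replicate 1 (blue) and replicate 2 (orange); the number of genes is in brackets. The dashed line marks the 4.68% of all protein-coding genes, and cytosolic ribosomal proteins reached 41.5%.

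No tissue list passed the test against other protein-coding genes in the consensus list. Cuticle collagen genes had 8 of 175 with a peak, led by col-103 (70.4), col-10 (69.9) and col-90 (57). Of the 8, col-90, sqt-3 and dpy-4 had no region in replicate 1, and col-103 had a signal of only 4.11 in replicate 2. The genes sqt-3 and dpy-4 were named after their values were seen. Epidermis and moulting regulators had 0 of 54, which allows a share of up to 5.56%. Intestinal genes had 4 of 78 (cpl-1 83.0, spp-2, spp-1 and cpr-4, the last named after its value was seen). Muscle structure genes had 3 of 45 (act-4 90.3, cpn-3 57.5 and mlc-3 40.5). Pan-neuronal and synaptic genes (0 of 38), neurotransmitter identity genes (0 of 20), neuropeptide genes (nlp-33 and nlp-76, of 143), germline maintenance genes (0 of 32), oocyte and eggshell genes (spn-4, of 30), vitellogenins (0 of 6) and major sperm proteins (0 of 31) were not called either. Nor was the core histone list, a rule on symbols (his-37, his-24, his-35 and, named after its value was seen, his-41, of 72). That rule also took in his-24, a linker histone gene. Cytochrome P450 genes (0 of 74), homeobox regulators (ceh-8 and ceh-38, of 87) and nuclear hormone receptors (12 of 274, led by nhr-49 with 68) were not called. The lowest adjusted p of these 15 lists was 0.110, for cytochrome P450 genes, by Fisher's exact test. Core histone windows had a median unique share of 3.82%, and the list was above other genes among those with at least 90% unique sequence (adjusted p = 0.00267, Fisher's exact test) but below by mean rank over the full lists (adjusted permutation p = 0.00110). That mean rank, which was not matched on gene length, also placed muscle structure (adjusted permutation p = 0.000367) and pan-neuronal and synaptic genes (0.000227) above other genes in both replicates, and major sperm proteins, neuropeptides and cytochrome P450 genes below. Cytochrome P450 genes were also below with interval overlap (adjusted p = 0.0475, Fisher's exact test). Of the 218 genes in the fixed microRNA list, 22 carried a peak. Without replicate 1, the highest-signal regions of replicate 2 had 18 collagen genes (adjusted p = 0.00200) and 7 epidermal genes (adjusted p = 0.0214), both above other genes by Fisher's exact test.

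X-linked genes carried peaks less often than autosomal ones. A peak was found at 76 of 2731 X-linked protein-coding genes (2.78%, interval 2.20 to 3.47) and at 858 of 17242 autosomal ones (4.98%, interval 4.66 to 5.31), a ratio of 0.559 (Fisher's exact test, two-sided p = 9.49e-08). The highest signals on X were at the non-coding genes C30E1.9 (379), tts-1 (274, also in the window of F09E10.10), R03E9.7, also in that of R03E9.10, and W05H9.3 (188). Among X-linked protein-coding genes the highest were at mdl-1 (148), a bHLH transcription factor gene, F09A5.3 (147), osm-11 (117), act-4 (90.3), an actin gene, and rpl-11.2 (86.4). The ratio was 0.471 in replicate 1 (p = 5.11e-11) and 0.715 in replicate 2 (p = 0.00211) by the same exact test. Where X-linked peaks existed, their signal did not differ detectably from that of autosomal peaks, with medians of 45.5 over 139 peaks and 47.2 over 1189 (log2 difference X minus autosomes -0.05, permutation p = 0.316). The consensus holds only regions with a pooled signal of 34.3 or more, on X and autosomes alike. A lower signal on X could therefore remove peaks without lowering the median, and the comparison covers only the peaks that remained. Chromosome X holds 17.7% of the nuclear genome and held 10.5% of consensus peaks. Chromosome III had most peaks per megabase, 18.9 against 7.84 on X, and the lowest autosome was IV with 11.5. Set beside protein-coding genes, X had 139 peaks and 2731 genes, V had 272 and 4994, and III had 261 and 2640. Whether X differs from each autosome alone was not tested.

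The replicates shared about as many of their strongest regions as they did not. Of the 1328 highest-signal regions of replicate 1, 48.0% met one of the 1328 highest of replicate 2, against a mean of 0.900% and at most 2.33% after shifting along the chromosomes (one-sided permutation p = 0.001, the smallest 1000 shifts can give). Of the consensus peaks, 1301 were found in both full lists, 619 (46.6%) met the highest-signal regions of both and 78 met those of neither. Those of replicate 1 were met by 1053 consensus peaks and those of replicate 2 by 816. Across consensus peaks, which are not independent, Spearman's rho of signal was 0.27 (bootstrap 95% interval 0.21 to 0.32) and Pearson's r of log2 signal was 0.41. The consensus holds the regions of highest pooled signal, and choosing peaks by a value that combines both replicates lowers their correlation, so these values describe the chosen peaks only. Among peaks found in both full lists, those that differed most in rank were as follows. They lay at anr-6 (33.6 in replicate 1 and 2.40 in replicate 2), M01H9.6 (35.1 and 2.60) and F57A10.2 (37.7 and 2.97). The others were an intergenic place on chromosome IV (6336742 to 6337081, 47.5 and 2.90) and, the other way round, sulp-6 (3.85 and 28.7). Peaks missing from 1 list have no rank there. Of the protein-coding genes in either set, 492 had a highest-signal region in both, from 922 in replicate 1 and 845 in replicate 2.

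Genes of the cuticle and of moulting differed between the replicates. In the highest-signal regions, collagen genes had 4 in replicate 1 and 18 in replicate 2, with 1 and 15 in that replicate alone (exact sign test over 26 lists, adjusted p = 0.0135). All protein-coding genes had 430 and 353 in 1 replicate alone there, and against that split of the other genes the collagens had an adjusted p of 0.00134 (Fisher's exact test). The gene col-103 ran the other way, with 64.9 in replicate 1 and 4.11 in replicate 2. For dpy-5 and sqt-1, collagen genes that shape the body, replicate 1 had no region and replicate 2 had signals of 32.4 and 33.9. The epidermis and moulting regulators had 1 and 7, which did not pass (adjusted p = 0.914 by the exact sign test and 0.337 by Fisher's exact test against other genes). Those 7 were nhr-23, blmp-1, lin-42, qua-1, ptr-18, mlt-11 and ptr-4, and the 1 was wrt-2. These 8 genes and the collagen genes dpy-5 and sqt-1 were named after their values were seen. In the full lists of 30000 regions, epidermal genes had 15 of 54 in replicate 1 and 44 in replicate 2 (adjusted p = 9.69e-08), and collagen genes 31 and 71 of 175 (adjusted p = 5.94e-06), by the exact sign test. All protein-coding genes also leaned to replicate 2 there, with 1570 in replicate 1 alone and 2009 in replicate 2 alone. Of all protein-coding genes, 42.6% had a region in replicate 1 and 44.8% in replicate 2. The share of collagen genes, 17.7% and 40.6%, was thus low in replicate 1 and not above that of all genes in replicate 2. The share of epidermal genes was 27.8% and 81.5%. Against the split of other genes, epidermal and collagen genes still differed (adjusted p = 1.95e-06 and 0.000425, Fisher's exact test). Intestinal genes (37 and 50 of 78, adjusted p = 0.0204) and chemoreceptors (70 and 99 of 1312, 0.0249) passed only the exact sign test, and not Fisher's exact test against other genes (adjusted p = 0.0569 and 0.237). Among other lists, germline maintenance (5 and 0), oocyte and eggshell (6 and 1) and translation factors (8 and 2) leaned to replicate 1. Muscle structure (1 and 6) and neuropeptides (9 and 24) leaned to replicate 2. These counts are genes in replicate 1 alone and in replicate 2 alone, in the full lists, and none of these lists passed either test. The tests between replicates were chosen after the values were seen, and 1 library on each side cannot separate the replicates' biology from their preparation.

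**Figure D4:**
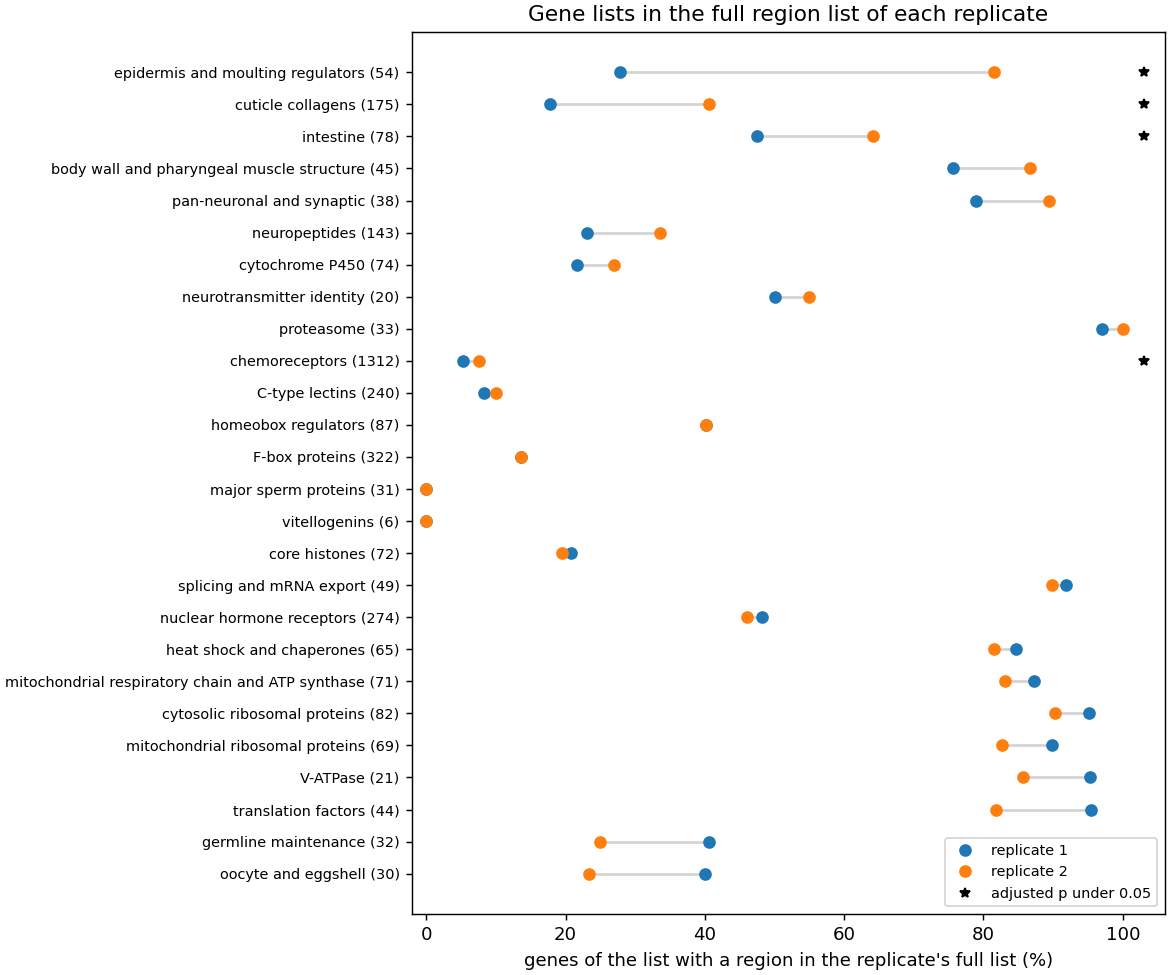
Percent of the genes of each list with a region in the full list of replicate 1 (blue) and replicate 2 (orange); the number of genes is in brackets, and stars mark an adjusted exact sign test p under 0.05. Epidermis and moulting regulators had 27.8% in replicate 1 and 81.5% in replicate 2, and cuticle collagens 17.7% and 40.6%. For all protein-coding genes the values were 42.6% and 44.8%.

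The same data processed on build ce10 gave a consensus list of 1380 regions, with 144 on chromosome X, against 1328 and 139 on ce11. The highest signal was 803 on both builds. Coordinates were not converted between builds.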

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

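The tests of weaker enrichment, shared reads, tRNA genes, unmappable sequence and gene length, and the sign tests between replicates, were chosen after the results they measure were seen. No biological explanation follows from the design, which has 1 group, and none was tested for the SL2 genes or the receptor families.

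Beyond the consensus list, the pooled list held 2152 further regions at the same upper limit of the −log10 q-value as every consensus peak, a signal in data the main comparisons did not use. Of these, 2007 were found in both replicate lists and 39.5% lay at 5' ends. They would add 1251 of the 19973 protein-coding genes, among them 20 of 82 cytosolic ribosomal protein genes, 15 of 71 of the respiratory chain, 14 of 65 chaperones, 13 of 49 of splicing and mRNA export and 10 of 33 of the proteasome. Nuclear hormone receptors would gain 14 of 274, a share no higher than that of all protein-coding genes.

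Collagen and epidermal genes carried more highest-signal regions in replicate 2 than in replicate 1, although of the 2 lists only the collagens passed the exact sign test there (adjusted p = 0.0135) and Fisher's exact test against the split of other genes (0.00134). The excess was 20 genes over both lists, where lists matched on GC content and length gave 0.357 on average and 14 at most, which argues against GC content and gene length as the whole cause. Weaker enrichment in replicate 1 was taken to lower its share of regions at 5' ends. That share was 43.4% of the highest-signal regions in replicate 1 and 37% in replicate 2, a difference of 6.48 percentage points (Fisher's exact test, p = 0.000765). The share is only an indirect measure of enrichment, and 48.0% of these regions of replicate 1 met one of replicate 2, so the sets are not independent. Its direction goes against weaker enrichment but does not exclude it. A difference in moulting phase may contribute and stays open, with its test under the other observations. Differences in preparation or in tissue makeup between the 2 populations were not tested and cannot be excluded. Intestinal genes leaned the same way in the full lists by the exact sign test (adjusted p = 0.0204), but not against the split of other genes (adjusted p = 0.0569, Fisher's exact test). Germline maintenance, oocyte and eggshell and translation factor genes leaned to replicate 1 there, and none of those lists passed either test.

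SL2 genes held the 3 highest signals. Reads shared between similar copies could raise them and stay open, since these 3 genes were 38.8% to 73.8% unique inside the gene. The relation of signal to unique share over the 18 genes cannot decide this (Spearman's rho 0.021, bootstrap 95% interval -0.47 to 0.54, permutation p = 0.932). It used only summits inside each gene's window. By that rule sls-2.7, sls-2.14 and sls-2.16 entered as having no signal and sls-2.17 with a signal of 6.97. Consensus summits lay just past the 3' ends of these genes, so their values in the relation are too low. Sequence inside sls-2.8 was 100% unique, and its signal of 229 was far above the median of 47. Sequence inside sls-2.18 and sls-2.9 was also 100% unique, and their signals of 43.5 and 43.1 lay below that median. The other gene at 100% was sls-2.16, which had no signal by the window rule. Signal at any short, highly transcribed gene also stays open, since tRNA genes carried a peak less often than snRNA genes other than SL1 and SL2 (2.94% against 9.09%, Fisher's exact test, p = 0.00738), but among genes at least 90% unique inside the gene 1 of 23 tRNA genes and 1 of 21 snRNA genes did. At that limit 5 of 8 SL2 genes did. Counted without a peak were also sls-2.14 and sls-2.16, although consensus summits lay just past their 3' ends. SL2 genes were picked for their signals and the 3 highest lay under the limit, so the count decides neither explanation. How reads with several matches were aligned is not given in the sources used here.

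Chemoreceptor and F-box genes rarely carried a peak. Sequence that cannot be mapped is unlikely as the whole cause, since among genes with at least 90% unique sequence 8 of 1324 carried one against 863 of 15386 other genes, a ratio of shares of 0.108 (Fisher's exact test, p = 7.09e-22). Gene length is likewise unlikely as the whole cause, since the 8 genes were 0.128 times the mean of lists matched on length (62.5 genes), and 0.145 times within the unique genes (permutation p = 0.0002 for both, the smallest these lists can give). Expression in few cells of the whole animal was not tested.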

How the results depend on the processing

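The restrictions to peaks strong in both replicates and to unique genes, the full-list tests between replicates and their tests against other genes were chosen after the data were seen. Of the values that answer a comparison, 76 kept their direction and side of the threshold or stayed within the set range, which for counts of lists is judged by size and not by which lists they are. The rank correlation of 0.27 was 0.17 with 50% reciprocal overlap and -0.060 when ranked by −log10 q-value, where most peaks tie at the upper limit by construction. Near 3' ends the share was 17.2% with a 1000 bp window (permutation p = 0.146). Summits are placed at 5' ends first, and 5' ends then held 59.1%. The fall in the 3' share with a wider window therefore follows from the order of the classes. Genes with a peak fell from 934 to 470 among consensus peaks above their median signal and 439 with peaks strong in both replicates, which hold fewer peaks by construction. Lists above other genes numbered 4 in each of these instead of 7, and 4 to 7 with 1 replicate left out, the 4 being without replicate 2, while the 7 without replicate 1 lacked mitochondrial ribosomal proteins and the proteasome and had cuticle collagens and epidermis instead. Lists below numbered 1 in each of these 2 smaller sets instead of 3, and 3 without replicate 1 and 2 without replicate 2. By mean rank over the full lists, which ranks all regions, 10 lists were above and 7 below. The protein-coding class, at 0.982 times random placement, was called above at 2.57 with summits near 5' ends only and 1.08 with interval overlap. It was called below at 0.889 without replicate 1 and 0.857 with a 250 bp window. Its windows join 5' ends, where summits lay at 2.29 times random placement, with gene bodies, where they lay at 0.460 times. What changed the call in each setting was not tested. Between replicates, intestinal genes and chemoreceptors leaned to replicate 2 in the full lists (adjusted p = 0.0204 and 0.0249, exact sign test), where the highest-signal regions held too few to give a direction. Neither passed against the split of other genes (adjusted p = 0.0569 and 0.237, Fisher's exact test), which leaned the same way. Among other values, 496 stayed the same, 28 lost and 18 gained a call, and 4 reversed, which are those of the protein-coding class above random placement and of the 2 full-list tests given here. With 1 replicate left out, 5' ends held 37% to 43.4% of summits. The overlap of replicates ranked by −log10 q-value was not run, since more regions tie at the limit than were compared. Sequencing depth is unknown, so its limit cannot be given.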

Other observations

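The shares by rank of region and the counts per list in the full lists were chosen after the data were seen.

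Strong regions lay nearer to gene starts than weak ones in both replicates. Among the first 3000 regions by signal, 40.5% of replicate 1 and 35.2% of replicate 2 lay at 5' ends, and among the last 3000 the shares were 21.4% and 19%. Chromosome X held 10.4% and 13% of the first 3000 regions and 13.2% and 19% of the last, for replicates 1 and 2. In the full lists of replicates 1 and 2, 42.6% and 44.8% of all protein-coding genes had a region. Of the 82 cytosolic ribosomal protein genes 78 and 74 did, and of the 33 proteasome genes 32 and 33. Major sperm protein and vitellogenin genes had none in either replicate. The median unique share of the windows of those 2 lists was 53.2% and 61.3%, and repeated sequence may hide a region there.

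A hypothesis for the collagen and epidermal genes is that the larvae of the replicates may have been in different phases of the moulting cycle, since cuticle genes are read in pulses before each moult. The labels give the age as unknown. It was tested on 137 genes of other moult-linked families (hedgehog-related and patched-related, cuticlins and apical matrix, and astacin proteases), none of them in the first lists, of which 34 had a region in the full list of replicate 1 and 69 in that of replicate 2. Among those with a region in 1 replicate only, 87.2% (41 of 47) were in replicate 2, against 54.9% of other protein-coding genes (Fisher's exact test, p = 4.30e-06). The hedgehog-related and patched-related list with the genes it shares with the first lists had 24 and 55 of 87, and without them 16 and 34 of 55, while cuticlins and apical matrix had 11 and 21 of 46, and astacin proteases 7 and 14 of 36. The values are consistent with a difference in phase, but a larger share of epidermal tissue or a difference in preparation would give them too, and neither of these was tested.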
